A study of Mus musculus with 6 samples.

How the data were processed

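Small RNA was measured by sequencing in 6 samples of mouse skin, 3 from mice exposed to ultraviolet A (UVA) light and 3 non-irradiated. The labels give each sample its group and its replicate number. Total RNA was isolated with the mirVana kit and the libraries were made with the TruSeq Small RNA kit, per the labels' protocols. Each column of the deposited tables was matched to a sample through the name in the sample's description.

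The deposited read counts are whole numbers per mature miRNA sequence and were used as they stand. Bowtie is named in the submitters' processing notes, and its version, the genome build and the miRNA database release are not given in the sources used here. The table holds 1480 entries, of which 1108 carry miRBase names and 372 are miRNAs predicted by the authors, which together took 0.041% of the reads. In 34 entries the authors merged identical mature sequences under joined names. The sequences are 17 to 27 nucleotides long. A further 2 lines were emptied before this work and were not analysed here. The deposited RPM values are the counts divided by a single constant per library, which gives each library's total reads as counted by the authors. The deposited log2 fold changes are the log2 ratio of the authors' mean normalized counts of the groups, and 692 of them are infinite because a mean is 0. Those means were recomputed from the counts with median-of-ratios size factors, with a largest relative deviation of 5.9e-15. The p-values and q-values of that table are the authors' own, per the file headers, and the tool behind them is not given in the sources used here.

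The libraries held 8194504 to 12817972 miRNA reads in the UVA group and 7653819 to 17192811 in the non-irradiated group. The floor used for a count of 0 was 3 counts per library, which is 0.191 to 0.437 counts-per-million (CPM) after scaling. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No pair of replicates agreed within sampling noise.

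The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filterByExpr filter and Benjamini-Hochberg adjustment. A miRNA was called at an adjusted p of 0.05 or lower. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts-per-million of the TMM-scaled library of tested miRNAs, given as mean ± SD over the 3 libraries of a group. Before the data were examined, 19 miRNA lists were fixed: epithelial, melanocyte, skeletal muscle, vascular, erythroid, leukocyte, mesenchymal, adipose, neural and liver markers, p53 targets, the miR-29 family, the let-7 family, the miR-17-92 clusters, the Dlk1-Dio3 region, Hox cluster miRNAs, injury and ultraviolet miRNAs, hair cycle miRNAs and the Sfmbt2 cluster. The 18 lists with 3 or more tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members past the threshold were counted over all tested miRNAs and adjusted over the list alone. Arm use was tested with limma on log2 of 5p reads plus 0.5 over 3p reads plus 0.5, in hairpins with 10 or more reads of each arm in each library. limma draws the variance of each hairpin toward a value shared over hairpins. Shares of reads were compared with an exact permutation test, 2-sided. The exact Clopper-Pearson 95% interval of each share in a single library had a half-width of at most 0.039 percentage points.

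The miRNAs named in the text follow a rule fixed before the data were examined: up to 12 per direction with the smallest p among called miRNAs whose groups did not overlap, the 5 most abundant, up to 4 abundant and up to 6 called members of each list, and the 4 hairpins with the smallest p for arm use. The text names a part of this set. miR-99a-5p, miR-143 as a hairpin in the arm comparison and the host and neighbour genes of hairpins were added after values were seen. Mature sequences were matched to the hairpins of the GENCODE annotation of GRCm38, and all coordinates are in GRCm38. Of 77 miRBase names checked for near-identical sequences, 31 lie within 2 edits of another sequence in the table. How the authors' counting split reads between such sequences is not given in the sources used here. The values of all 31 are therefore uncertain to that extent, also where the text does not repeat it. Among them are miR-27a-3p and miR-199a-5p, each 1 edit from its b form. miR-146a-5p and miR-24-1-5p are each 2 edits from a relative.

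Each test was first checked on simulated counts of the 499 tested miRNAs, with 200 of them changed for the edgeR and arm steps. The edgeR step called 5.07% of 2-fold, 36.7% of 4-fold and 67.0% of 8-fold changes, with 2.43% false calls. The list step, run with a single list raised 4-fold and all else unchanged, called 5 of 5 shifted lists and 0 of the others. The simulated miRNAs were drawn independently, so this check cannot tell how the list step behaves when members are correlated. In the data the estimated correlation was 0.119 in the Dlk1-Dio3 list and 0.41 in the let-7 list. The arm step called 31.1% of the changed hairpins, and 3 of its 79 calls were false.

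Other settings fixed beforehand were DESeq2 size factors, upper-quartile factors, library size without TMM, scaling without the 10 most abundant miRNAs, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 10 counts in each library, known miRNAs only, the replicate number as a block, an adjusted p of 0.1, a 2-fold minimum, other count minimums and pseudocounts for arm use, shares without the most abundant miRNA, and each library left out in turn. Settings chosen after seeing the data were the authors' total reads as library size, an offset for GC content, and the fits without non-irradiated replicates 1 and 2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Predicted miRNAs are named in the text only where the rule selects them.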

Results

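Mature miRNAs were counted by small RNA sequencing in skin of mice irradiated with UVA every other day for 4 months, to a total of 89.88 J/cm2, and in skin of non-irradiated mice. Each group had 3 libraries. Replicates 1, 2 and 3 held 12817972, 11390088 and 8194504 miRNA reads in the UVA group and 14546120, 17192811 and 7653819 in the non-irradiated group. The labels do not say that replicates are separate animals, so the p-values measure only the spread between these samples. The authors' total reads, of which miRNA reads made up 58.5%, 53.3% and 40.03% in the UVA libraries and 49.3%, 56.4% and 28.4% in the non-irradiated libraries, were 20.5 to 21.9 M in the UVA group and 26.9 to 30.5 M in the non-irradiated group. These totals do not overlap between the groups (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 allows), and a batch that follows them cannot be told apart from the treatment.

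The libraries also differed in how many miRNAs were seen. At least 1 read was present for 1096, 1099 and 1088 miRNAs in the UVA libraries and for 506, 574 and 715 in the non-irradiated libraries. Non-irradiated replicates 1 and 2 held 21 and 34 miRNAs with 1 to 9 reads and replicate 3 held 299, while the UVA libraries held 579, 591 and 582. miRNAs with 10 or more reads numbered 517, 508 and 506 in the UVA libraries and 485, 540 and 416 in the non-irradiated libraries.

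**Figure D1:**
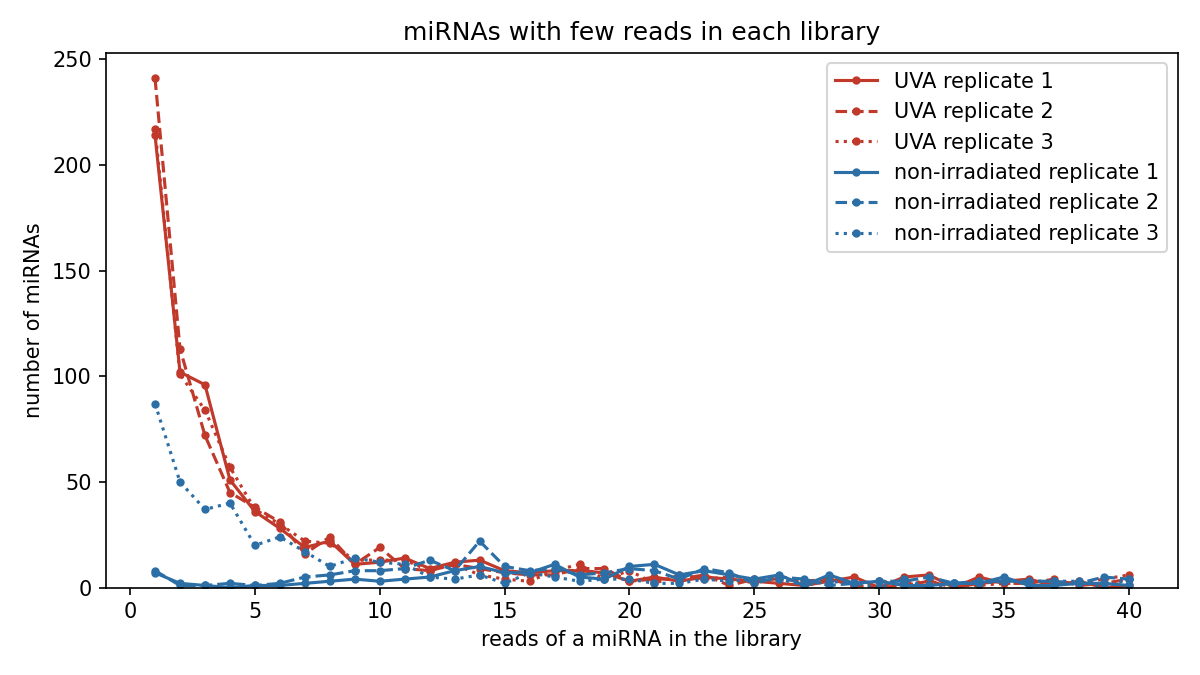
Number of miRNAs with each number of reads per library (x axis, 1 to 40 reads; y axis, number of miRNAs), with 1 line per library. UVA replicates 2 and 3 have 241 and 217 miRNAs with a single read, against 7, 8 and 87 in the non-irradiated libraries.

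The question of the first comparison was which skin miRNAs differ after repeated UVA exposure. The largest rise among the named miRNAs with reads in both groups was in both arms of miR-31, a miRNA known from wounded and hyperproliferative epidermis. miR-31-5p rose from 4.49 ± 1.98 CPM to 324.5 ± 198 CPM (mean ± SD, n = 3 per group; log2 fold change 6.17, SE 0.74, edgeR adjusted p = 0.00196), and miR-31-3p rose with a log2 fold change of 6.22 (SE 1.20, edgeR adjusted p = 0.00804). The merged miR-199a-3p/miR-199b-3p, which is typical of fibroblasts, rose from 1800 ± 319 to 17600 ± 4986 CPM (n = 3 per group). miR-205-5p, a keratinocyte miRNA, rose from 672 ± 196 to 5256 ± 2057 CPM and miR-29a-3p, which targets collagen mRNAs, from 423 ± 113 to 3415 ± 1507 CPM. The 3p arm of miR-205 was not called, at 76.9 ± 11.9 CPM in UVA and 79.4 ± 9.50 CPM in non-irradiated skin (log2 fold change -0.048). The strongest falls by p were in miR-1a-3p, the main miRNA of striated muscle, from 362200 ± 70710 to 36980 ± 17160 CPM (log2 fold change -3.29, SE 0.43, edgeR adjusted p = 0.00196), and in miR-411-5p of the imprinted Dlk1-Dio3 region, from 3380 ± 296.9 to 303 ± 98.6 CPM (log2 fold change -3.48, SE 0.45, edgeR adjusted p = 0.00196).

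Other miRNAs that rose were miR-211-5p (log2 fold change 4.62, SE 0.80), which lies in the melanocyte gene Trpm1, miR-210-3p (3.96, SE 0.73), a miRNA induced in hypoxia, and miR-221-3p (3.23, SE 0.57), which targets the mRNAs of Kit and p27. miR-126b-5p (2.96, SE 0.55), from the strand opposite an Egfl7 exon, and miR-98-5p (2.79, SE 0.54) of the let-7 family rose as well, at edgeR adjusted p from 0.00628 to 0.00795 for these 5. The 5p arm of miR-221 had a log2 fold change of -0.49 and was not called (edgeR adjusted p = 0.551). The UVA mean of miR-211-5p was 174.5 CPM and was 75.73 CPM without UVA replicate 2. miR-182-3p and miR-210-5p had no read in the non-irradiated libraries and reached 4.87 ± 1.91 and 6.70 ± 5.06 CPM in the UVA libraries, at least 16.0-fold and at least 22.0-fold higher than a floor of 3 counts per library. The UVA mean of miR-210-5p was 3.803 CPM without UVA replicate 3. That floor does not cover the scarcity of low counts in non-irradiated replicates 1 and 2, which bears on each of the 10 called miRNAs without a read in the non-irradiated group.

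miRNAs that fell included miR-10b-5p of the Hoxd cluster, from 59350 ± 31930 to 5581 ± 665 CPM (log2 fold change -3.41, SE 0.49, edgeR adjusted p = 0.00288), and miR-122-5p, the main hepatocyte miRNA, from 101.5 ± 50.7 to 6.18 ± 4.00 CPM (-4.04, SE 0.72). miR-100-5p fell by 2.85 on the log2 scale (SE 0.39) while miR-99a-5p, chosen after its values were seen because it differs from miR-100-5p by 1 edit, rose by 1.80 (SE 0.36, edgeR adjusted p = 0.00909). Reads of that pair, of miR-10a-5p and miR-10b-5p, of miR-211-5p and miR-204-5p, and of miR-29a-3p and miR-29c-3p could be split differently by another counting rule, and their values are uncertain to that extent. miR-1981-5p fell by 3.11 (SE 0.59), and a predicted miRNA without a miRBase name had a log2 fold change of -9.60 (SE 1.61, edgeR adjusted p = 0.00555; no adjusted p by the DESeq2 Wald test), from 564 ± 737 to 0.751 ± 0.896 CPM. Its non-irradiated mean was 138.3 CPM without replicate 2, and without UVA replicate 3 the UVA means of this miRNA and of miR-122-5p were 0.2551 and 4.042 CPM.

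**Figure D2:**
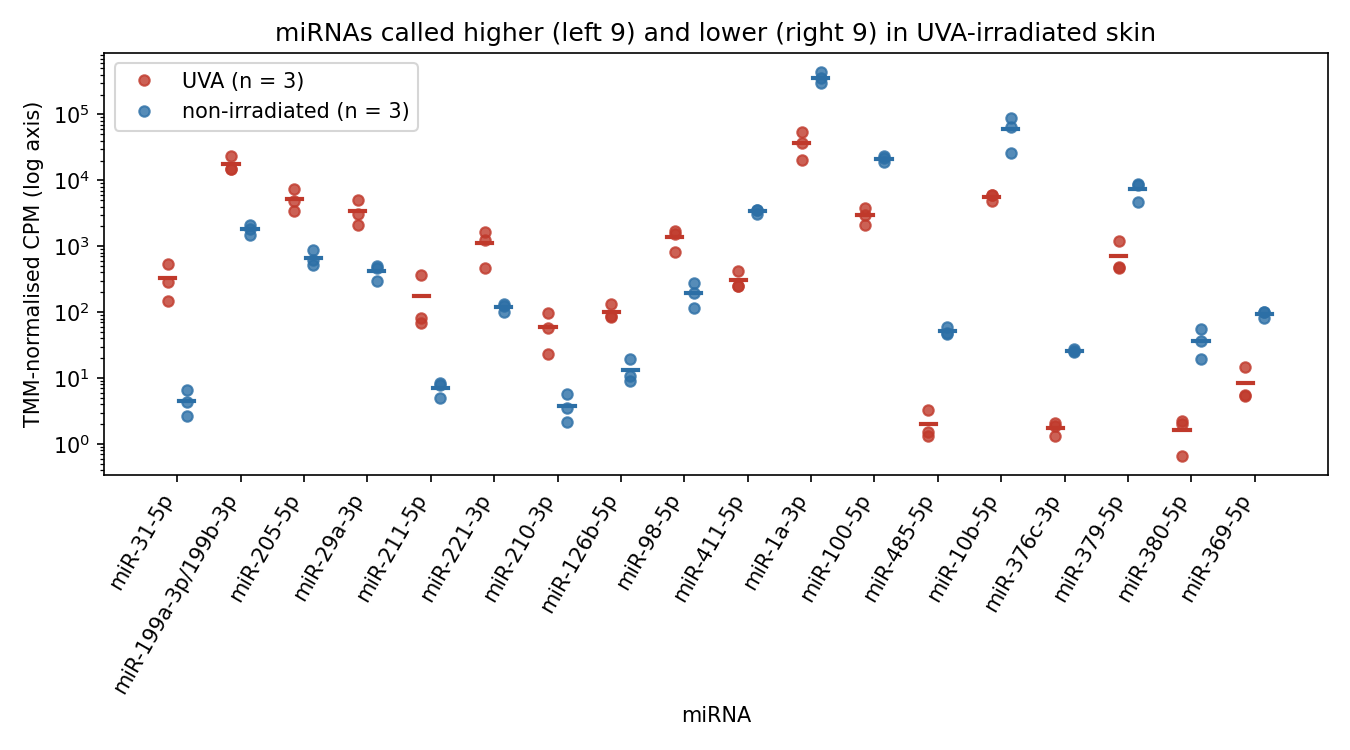
CPM in each library for 9 miRNAs called higher (left) and 9 called lower (right) in UVA skin, on a log axis; points are libraries and bars are group means of 3 libraries. For each of these miRNAs the 3 UVA libraries lie on one side of the 3 non-irradiated libraries, as for miR-31-5p with means of 324.5 and 4.49 CPM.

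In GRCm38 the hairpin of miR-31 lies on chromosome 4 at 88910557 to 88910662, minus strand, in an exon of a long non-coding RNA. Mir205 lies on chromosome 1 at 193507463 to 193507530, minus strand, also in a non-coding exon, and Mir211 on chromosome 7 at 64205806 to 64205911, plus strand, in an intron of Trpm1. miR-1a-3p can come from Mir1a-1 on chromosome 2 at 180389048 to 180389124, plus strand, and from Mir1a-2 on chromosome 18 at 10785481 to 10785552, minus strand, opposite an intron of Mib1. Mir10b lies on chromosome 2 at 74726070 to 74726137, plus strand, in introns of Hoxd3 and Hoxd4.

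Of 499 miRNAs tested with edgeR's quasi-likelihood test, 109 were called, 68 higher and 41 lower in UVA skin, and 203 had an unadjusted p of 0.05 or lower. All 109 had groups that did not overlap, as had 48.3% of the tested miRNAs against 10% by chance for 3 against 3. The median log2 fold change of all tested miRNAs was 0.27, and with library size alone it was 0.81, with 122 called higher and 27 lower. With the authors' total reads as library size, chosen after seeing the data, it was 1.06, with 22 of 167 called miRNAs lower. The 109 calls became 38 without UVA replicate 2, 57 without non-irradiated replicate 1, 63 without non-irradiated replicate 2, and 1, miR-10b-5p, without both of these non-irradiated libraries. Among the miRNAs named above, the calls of miR-182-3p (adjusted p = 0.054 without UVA replicate 2), miR-98-5p (0.0557 without non-irradiated replicate 1) and miR-99a-5p (0.0669 and 0.0547 without non-irradiated replicates 1 and 2 in turn) rested on single libraries.

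In the authors' deposited table, 190 of 1480 miRNAs had a p of 0.05 or lower, 120 higher and 70 lower. The authors' deposited table has 59 miRNAs with a q of 0.05 or lower, 36 higher and 23 lower. Of the 109 miRNAs called with edgeR, 52 were among those 59, all 52 in the same direction.

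The next comparison asked whether miRNAs of the lists moved together. At the preset correlation camera called 6 lists, but also 2 to 5 in each other split of the libraries 3 against 3. The camera calls below carry that limit. The miRNAs of the Dlk1-Dio3 region, an imprinted cluster expressed from the maternal chromosome, had 14 of 58 tested members lower, none higher and 44 not called, and 52 of 58 had negative log2 fold changes (median -1.22). The list was lower by camera (adjusted p = 2.11e-10; adjusted p = 0.418 with an estimated correlation). The mean log2 CPM of the list was 3.01 ± 0.43 in UVA and 4.54 ± 0.21 in non-irradiated skin (difference -1.53, SE 0.28), and that of the skeletal muscle list was 6.79 ± 0.24 and 7.77 ± 0.21 (difference -0.98, SE 0.18; exact permutation test, 2-sided, p = 0.1 for both). With library size alone these differences were -1.03 (SE 0.29) and -0.45 (SE 0.23) and 43 of 58 members of the Dlk1-Dio3 list were negative, and with the authors' total reads they were -0.82 (SE 0.18) and -0.23 (SE 0.32) with 38 of 58 negative. miR-379-5p fell from 7370 ± 2254 to 714 ± 413 CPM (n = 3 per group), miR-485-5p from 51.9 ± 7.02 to 2.04 ± 1.08 CPM, miR-376c-3p from 26.0 ± 1.54 to 1.73 ± 0.386 CPM and miR-380-5p from 37.1 ± 18.4 to 1.65 ± 0.871 CPM. The UVA mean of miR-379-5p was 476 CPM without UVA replicate 3. The abundant miR-127-3p had a log2 fold change of -1.25 and was not called (edgeR adjusted p = 0.0799). The 93 entries of the list match 52 hairpins within 184.3 kb of chromosome 12, from 109563692 to 109747960 in GRCm38. Adjusted over the list alone, 15 members fell. The count of members that fell was 6 without UVA replicate 2, 22 without UVA replicate 3, and 0 without non-irradiated replicates 1 and 2, and was 9 with the authors' total reads and 23 with limma-voom. The list lay lower in each scaling tried for the lists.

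**Figure D3:**
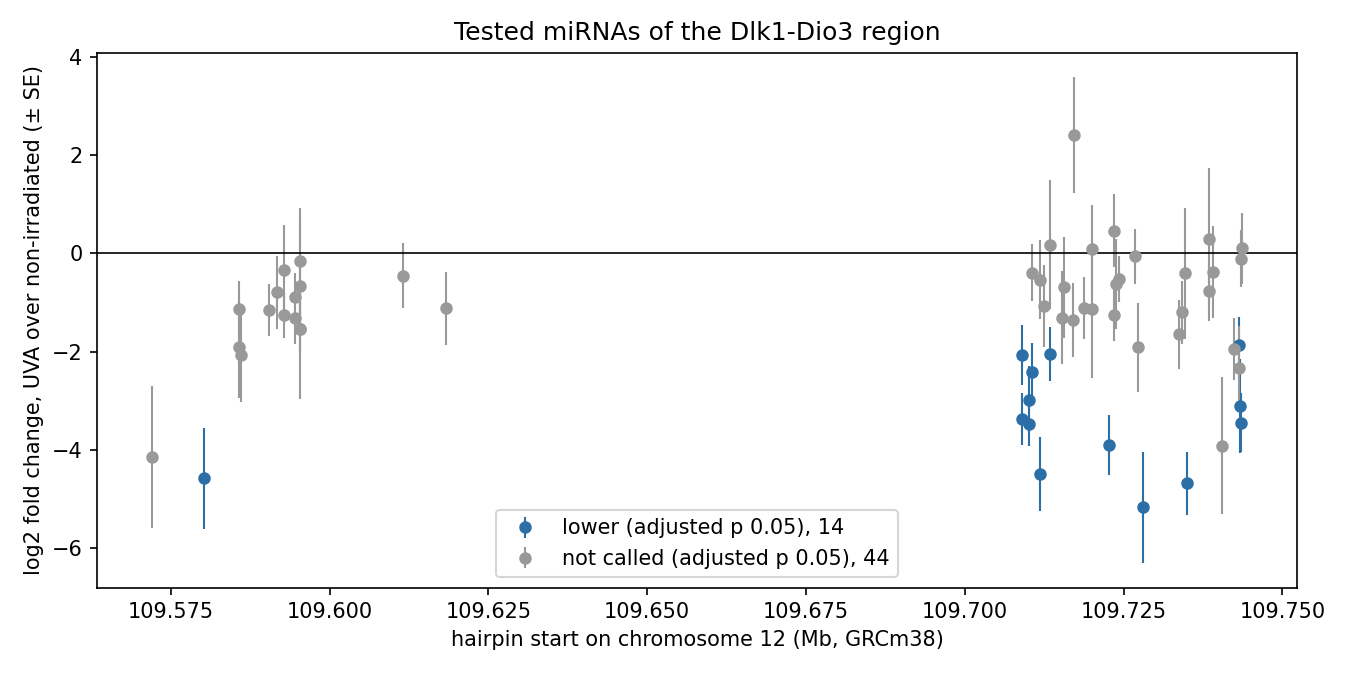
Log2 fold change of UVA over non-irradiated skin (y axis, points with SE bars) against position on chromosome 12 in GRCm38 (x axis) for the 58 tested miRNAs of the Dlk1-Dio3 list. The 14 called miRNAs are all lower in UVA skin, and 44 are not called.

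The Sfmbt2 list, fixed by the names of miRNA families, had negative log2 fold changes in 14 of 14 tested members (median -1.56). The hairpins matched to miR-467a-5p and to the merged miR-669a-5p/miR-669p-5p lie in introns of Sfmbt2, and those of the other members were not located. The merged miR-669a-5p/miR-669p-5p fell from 30.9 ± 5.14 to 8.94 ± 3.65 CPM (n = 3 per group), and 13 members were not called, such as miR-467a-5p with a log2 fold change of -1.79 (SE 0.77). The UVA mean of miR-467a-5p was 43.68 CPM and was 18.15 CPM without UVA replicate 1. When adjusted over the list alone, 0 members fell by edgeR, and 6 had an unadjusted p of 0.05 or lower. With library size alone and with the authors' total reads, 0 members were called by edgeR over all miRNAs and 0 had an unadjusted p of 0.05 or lower, and 13 and 12 of the 14 were negative. The DESeq2 Wald test called 5 lower and limma-voom 3. With TMM scaling, edgeR called 3 lower without UVA replicate 3, 2 without non-irradiated replicate 2 and 1 without UVA replicate 1. It called 0 without each other single library. The list was lower by camera (adjusted p = 0.0117; adjusted p = 0.418 with an estimated correlation). The call of miR-669a-5p was lost without each single library except UVA replicate 3, with adjusted p from 0.0551 to 0.166.

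In the let-7 family, which rises as cells differentiate, 7 of 20 tested members rose, none fell and 13 were not called, and 20 of 20 had positive log2 fold changes. let-7d-5p rose from 598 ± 178 to 4270 ± 2767 CPM and let-7i-5p from 19080 ± 2046 to 52610 ± 30760 CPM (n = 3 per group). let-7f-5p, the most abundant member, had a log2 fold change of 0.24 and was not called (edgeR adjusted p = 0.637), and it was negative without non-irradiated replicate 2 (-0.23). With p adjusted over the list alone, 8 members rose, and over all miRNAs 11 rose with library size alone and 11 with the authors' total reads. The list was higher by camera (adjusted p = 0.0116; adjusted p = 0.528 with an estimated correlation). Without non-irradiated replicate 2 the list was not called (adjusted p = 0.0778), and the count of members that rose was 2 without this library, 2 without UVA replicate 2 and 1 without non-irradiated replicate 1. It was 4 without non-irradiated replicate 3. The call of let-7i-5p was lost without each single library except UVA replicate 1, with adjusted p from 0.0928 to 0.143. Several let-7 sequences lie within 2 edits of each other, so the split between members is uncertain.

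Fibroblast miRNAs of the miR-199 and miR-214 group rose in 3 of 5 tested members, with none lower. miR-199a-5p rose from 1163 ± 585 to 4050 ± 444 CPM and miR-214-5p from 81.7 ± 10.1 to 398 ± 129 CPM (n = 3 per group). The hairpins Mir199a-2 and Mir214 lie in exons of the non-coding RNA Dnm3os. miR-199a-5p can also come from Mir199a-1 on chromosome 9, opposite an intron of Dnm2, and which hairpin gave its reads is not known. In this list 4 members rose when adjusted over the list alone. The list was higher by camera (adjusted p = 0.033; adjusted p = 0.418 with an estimated correlation). The list call was lost without UVA replicate 1 and without each of the 3 non-irradiated libraries (adjusted p from 0.0704 to 0.142), and 1 member rose without non-irradiated replicates 1 and 2 in turn. miR-199a-5p lost its call without UVA replicate 2 and without non-irradiated replicates 1 and 2 in turn (adjusted p from 0.0965 to 0.147), and miR-214-5p without each of the latter 2 (0.0734 and 0.0687).

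The miR-17-92 clusters, known for promoting proliferation, had 3 of 17 tested members higher, none lower and 14 not called. miR-17-5p rose from 83.8 ± 45.1 to 354 ± 181 CPM, miR-106b-5p from 28.9 ± 15.1 to 151 ± 88.7 CPM and miR-92a-3p from 11.4 ± 2.11 to 57.0 ± 29.6 CPM (n = 3 per group). The count was also 3 when adjusted over the list alone. It was 1 with upper-quartile factors, 8 with library size alone, 8 with the DESeq2 Wald test, 6 with limma-voom and 11 with the authors' total reads. It was 0 without UVA replicate 2 and without non-irradiated replicates 1 and 2 in turn, with 5, 5 and 2 members higher at an unadjusted p of 0.05 by edgeR. The list was higher by camera (adjusted p = 0.0366; adjusted p = 0.442 with an estimated correlation). The list call was lost without UVA replicate 1 and non-irradiated replicates 1 and 2 in turn (adjusted p from 0.0593 to 0.125). miR-17-5p and miR-106b-5p lost their calls without each single library except UVA replicate 3 (adjusted p from 0.0609 to 0.18), and miR-92a-3p without UVA replicate 2 and each non-irradiated library (0.0622 to 0.104).

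Of the miRNAs described in wound or ultraviolet responses of skin cells, 6 of 23 tested members rose, none fell and 17 were not called. Besides both arms of miR-31, miR-146a-5p, which is induced by inflammatory signalling, rose from 1843 ± 308 to 4385 ± 1177 CPM and miR-27a-3p from 3130 ± 579 to 9015 ± 1603 CPM (n = 3 per group). miR-21a-5p, widely raised in injured tissue, was at 32940 ± 12840 and 26820 ± 5167 CPM and was not called, and its sign was positive with library size alone. Adjusted over the list alone, 10 members rose and 1 fell. Over all miRNAs, 11 rose with library size alone, 12 with the authors' total reads and 11 with the DESeq2 Wald test, none lower, while 4 rose and 1 fell with upper-quartile factors. The list was higher by camera (adjusted p = 0.0459; adjusted p = 0.418 with an estimated correlation). The list call was lost without UVA replicate 1 and without each of the 3 non-irradiated libraries (adjusted p from 0.0787 to 0.153), and 2 members rose without non-irradiated replicates 1 and 2 in turn. miR-146a-5p lost its call without each single library except UVA replicate 3 (0.119 to 0.254), and miR-27a-3p without UVA replicate 2 and each non-irradiated library (0.054 to 0.103).

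Hair cycle miRNAs shared their called members with the lists above: 5 of 13 rose, both arms of miR-31, miR-214-5p, miR-24-1-5p and miR-24-2-5p, and none fell. miR-24-2-5p was at 2419 ± 2120 CPM in UVA skin and 600.5 ± 66.8 CPM in non-irradiated skin (n = 3 per group), and its UVA mean was 1204 CPM without UVA replicate 1. The more abundant miR-24-3p went the other way without a call, at 12700 ± 1986 CPM in UVA and 18100 ± 1037 CPM in non-irradiated skin. Its log2 fold change was -0.511 and turned positive with library size alone. miR-22-3p had a log2 fold change of -1.156 (edgeR adjusted p = 0.064). In all, 9 members were positive and 4 negative. Adjusted over the list alone, 7 members rose and 1 fell. The list was not called by camera (adjusted p = 0.127) and was called higher by fry (adjusted p = 0.00742), and 2, 2 and 3 members rose without non-irradiated replicates 1, 2 and 3 in turn. miR-24-1-5p and miR-24-2-5p lost their calls without UVA replicate 1 and each non-irradiated library (adjusted p from 0.0668 to 0.151).

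Markers of the cell types that skin holds moved in different directions. Of 7 skeletal muscle miRNAs, miR-1a-3p fell, miR-133b-3p rose from 90.0 ± 35.7 to 322 ± 178 CPM (n = 3 per group) and 5 were not called. miR-133a-3p, made from hairpins next to those of miR-1a, was at 423 ± 203 CPM in UVA skin and 430 ± 88.5 CPM in non-irradiated skin, with a sign that changed with the scaling, and it differs from miR-133b-3p by 1 edit. miR-206-3p was at 12500 ± 14830 and 27850 ± 11830 CPM (edgeR adjusted p = 0.26), and its UVA mean was 3936 CPM without UVA replicate 3, where it was called lower (adjusted p = 0.00762) and 2 muscle members were lower in all. Of 13 epithelial miRNAs, miR-205-5p and miR-141-5p rose, while miR-203-3p, the miRNA of differentiating keratinocytes, was at 50940 ± 24470 and 42460 ± 5238 CPM and was not called. The 3p arm of miR-205 was not called either. Of 4 miRNAs of the melanocyte list, both arms of miR-211 rose, and its relative miR-204-5p had a log2 fold change of -1.35 (SE 0.52, edgeR adjusted p = 0.0812). miR-211-3p had no read in the non-irradiated group and was at least 10.6-fold higher. The median of this list was 2.12, or 1.51 with that miRNA at its bound. Single libraries decided the calls of miR-133b-3p (lost without UVA replicate 2 and each non-irradiated library, adjusted p from 0.0604 to 0.197), miR-141-5p (lost without each library except UVA replicate 3, 0.0861 to 0.3) and miR-211-3p (0.0796 without UVA replicate 2).

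Of 7 vascular miRNAs, the endothelial miR-126a-5p fell by 2.12 (SE 0.56) and the smooth muscle miR-143-3p by 1.59 (SE 0.42) on the log2 scale, while miR-126b-5p and miR-143-5p rose. The more abundant arm miR-126a-3p was not called, at 19390 ± 5928 CPM in UVA and 22280 ± 2948 CPM in non-irradiated skin (log2 fold change -0.20). In this list the median (-0.20) and the camera direction differ in sign from the mean (0.14). Of 8 leukocyte miRNAs, miR-146a-5p rose and miR-150-5p, a lymphocyte miRNA, fell from 382 ± 84.0 to 134 ± 35.7 CPM (n = 3 per group). None of 6 erythroid miRNAs was called by edgeR in the main fit (0 by the DESeq2 Wald test, 1 lower by limma-voom, and 1 lower by edgeR with scaling without the 10 most abundant miRNAs, no filter, the GC offset, the replicate block or without UVA replicate 3), and the merged miR-486a-5p/miR-486b-5p was the single member with an unadjusted p of 0.05 or lower (log2 fold change -1.54, adjusted p = 0.0661). The UVA mean of miR-486a-5p/miR-486b-5p was 463.7 CPM and was 293.4 CPM without UVA replicate 3. Of 9 adipose miRNAs miR-365-1-5p fell, from 150 ± 7.45 to 13.1 ± 8.83 CPM, and of 5 neural miRNAs miR-338-3p rose, from 13.2 ± 3.02 to 57.6 ± 14.1 CPM. The liver list, fixed beforehand as a control, had miR-122-5p as its single tested member and was not tested as a list. This control was not level: miR-122-5p fell by 4.04 on the log2 scale (edgeR adjusted p = 0.00673), and the cause was not tested. The calls of miR-126a-5p (adjusted p from 0.0667 to 0.104), miR-143-3p (0.054 to 0.103), miR-143-5p (0.0648 to 0.145), miR-150-5p (0.0578 to 0.104) and miR-338-3p (0.0717 to 0.109) were lost without UVA replicate 2 and without 2 to 4 other single libraries each.

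Adjusted over the list alone, 1 epithelial member rose, 2 melanocyte members rose and 1 fell, 1 muscle member rose and 1 fell, 2 vascular members rose and 2 fell, 2 leukocyte members rose and 1 fell, 1 neural member rose and 1 adipose member fell. Over all miRNAs, the 2 epithelial members that rose became 4 with library size alone, 7 with the authors' total reads, 3 with the DESeq2 Wald test, and 1 with limma-voom and with upper-quartile factors. With library size alone 2 vascular, 2 leukocyte and 2 adipose members rose, and with the authors' total reads 3, 3 and 2, while 1 adipose member fell in both. No vascular or leukocyte member was called lower by edgeR in these settings (2 vascular members at an unadjusted p of 0.05 with library size alone and 0 otherwise), against 2 and 1 by the DESeq2 Wald test and 2 and 2 by limma-voom. By camera the adjusted p was 0.148 for skeletal muscle, 0.261 for epithelial, 0.36 for melanocyte, 0.962 for vascular, 0.263 for erythroid, 0.969 for leukocyte, 0.443 for adipose and 0.969 for neural miRNAs. None of these lists was called by camera. fry, which asks if a list moved one way without comparing it with other miRNAs, called skeletal muscle lower (adjusted p = 0.0356) and epithelial higher (adjusted p = 0.0492).

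Among the other lists, miR-34a-5p, a direct p53 target, rose from 21.2 ± 9.92 to 112 ± 60.6 CPM (n = 3 per group) as the single called member of 7 p53 targets, and miR-192-5p had a log2 fold change of -1.60 (edgeR adjusted p = 0.0533). In the miR-29 family 2 of 5 members rose, miR-29a-3p and miR-29c-5p, and miR-29b-3p had a log2 fold change of 2.56 (edgeR adjusted p = 0.0585). The UVA mean of miR-29b-3p was 127.8 CPM and was 43.53 CPM without UVA replicate 1. Of 9 Hox cluster miRNAs, miR-10a-5p, miR-10b-5p and miR-196a-1-3p fell and miR-10a-3p rose. The median of this list (1.20) and its mean (0.42) were positive while camera gave the lower direction. The balance of called Hox members turned with the scaling, with 3 higher and 1 lower with library size alone and 5 higher and 1 lower with the authors' total reads, and was 3 and 3 with the DESeq2 Wald test and 2 and 3 with limma-voom. In the same 4 settings 2, 4, 3 and 1 of the p53 targets and 3, 4, 3 and 2 of the miR-29 members rose. Without UVA replicate 3 the miR-29 count was 4, and without each other single library it was 1. Without UVA replicate 1, 2 p53 targets were higher and 1 lower, and 2 Hox members were higher and 2 lower. When adjusted over the list alone, 2 p53 targets rose and 1 fell, 3 miR-29 members rose, and 4 Hox members rose and 3 fell. The camera adjusted p was 0.91, 0.114 and 0.962 for these 3 lists, none of which was called by camera, while fry called the miR-29 list higher (adjusted p = 0.0492). miR-34a-5p lost its call without UVA replicate 2 and each non-irradiated library (adjusted p from 0.0651 to 0.113), miR-29c-5p without each library except UVA replicate 3 (0.0723 to 0.142), miR-10a-3p without UVA replicate 2 and each non-irradiated library (0.0788 to 0.129), miR-10a-5p without replicate 3 of either group (0.0578 and 0.0588), and miR-196a-1-3p without 4 of the single libraries (0.0541 to 0.164).

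In the fit without non-irradiated replicates 1 and 2, chosen after seeing the data because these libraries lack low counts, the lone non-irradiated library is assumed to vary like the UVA libraries. The Dlk1-Dio3 and Sfmbt2 lists were lower by camera there (adjusted p = 1.12e-11 and 0.000302 at the preset correlation of 0.01; the estimated correlation was not run there and gave adjusted p = 0.418 for both in the full fit), with 0 members called by edgeR in either and 21 and 6 lower at an unadjusted p of 0.05. The let-7, miR-199 and miR-214, miR-17-92 and injury lists were not called there, and 1, 1, 0 and 3 of their members were higher at an unadjusted p of 0.05.

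The composition of the libraries was compared next. miR-1a-3p took 4.49% ± 2.13 of the miRNA reads in UVA skin and 29.9% ± 5.46 in non-irradiated skin (SD, n = 3 per group), a difference of -25.4 percentage points. The 10 miRNAs with the highest mean CPM over the 6 libraries took 59.5% ± 6.04 and 74.3% ± 2.33, a difference of -14.764 percentage points. When miR-1a-3p was left out of the list and of the total, the next 10 differed by -3.004 percentage points (exact permutation p = 0.5). That difference was -5.494 without UVA replicate 1 and -0.674 without non-irradiated replicate 2. miR-143-3p took 3.71% ± 0.377 in UVA skin and 7.49% ± 3.55 in non-irradiated skin, miR-26a-5p 7.56% ± 1.49 and 4.31% ± 0.679, and let-7f-5p 6.60% ± 1.63 and 3.86% ± 0.99. For these 5 shares the groups did not overlap, and the exact permutation test, 2-sided, gave p = 0.1 for each, the smallest that 3 against 3 allows. Shares add up to a fixed total, so the fall of miR-1a-3p by itself raises the shares of miR-26a-5p and let-7f-5p. Those 2 shares were not compared without miR-1a-3p, and let-7f-5p was not called by edgeR (log2 fold change 0.24, adjusted p = 0.637). The difference of -3.781 percentage points for miR-143-3p was -1.897 without non-irradiated replicate 2. miR-148a-3p took 11.6% ± 8.93 and 14.0% ± 5.40 (exact permutation p = 0.6), with a UVA mean of 6.39% without UVA replicate 1, and its difference turned positive without UVA replicates 2 and 3 and non-irradiated replicate 2 in turn (0.171, 0.009 and 0.618 percentage points).

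The last comparison asked whether the arms of a hairpin kept their ratio, which does not depend on the scaling between libraries. Both arms of miR-10a, a Hox cluster miRNA, were called, with miR-10a-5p lower (27240 ± 10000 to 8154 ± 3437 CPM) and miR-10a-3p higher (37.1 ± 11.01 to 174 ± 118 CPM, n = 3 per group; UVA mean 105.3 CPM without UVA replicate 2). The log2 ratio of 5p to 3p reads changed by -3.81 (SE 0.74, limma adjusted p = 3.84e-05) in miR-10a and by -3.69 (SE 0.74, adjusted p = 5.89e-05) in miR-10b. It changed toward the 5p arm in miR-674 (4.16, SE 0.78) and miR-708 (3.88, SE 0.75, limma adjusted p = 3.84e-05 for both). The SEs were nearly alike over the tested hairpins (0.729 to 0.796), because limma drew each variance toward a value shared by all. These SEs and p-values therefore do not measure each hairpin's own spread. In miR-674 the SD of the log2 ratio was 0.821 in UVA and 2.105 in non-irradiated skin. miR-143, a hairpin chosen here after its values were seen, changed by 3.55 (SE 0.75) with its 5p arm higher and its 3p arm lower.

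Of 74 hairpins with both arms measured, 27 were called by limma, 11 toward the 5p arm and 16 toward the 3p arm, and 30 had an unadjusted p of 0.05 or lower. In 32 of the 74 the arms had log2 fold changes of opposite sign. The count was 16 without non-irradiated replicate 2, 18 without non-irradiated replicate 3, and 4 without non-irradiated replicates 1 and 2, where miR-708 was not called (adjusted p = 0.125). None of the 8 hairpins with 1000 or more reads of both arms in each library was called.

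**Figure D4:**
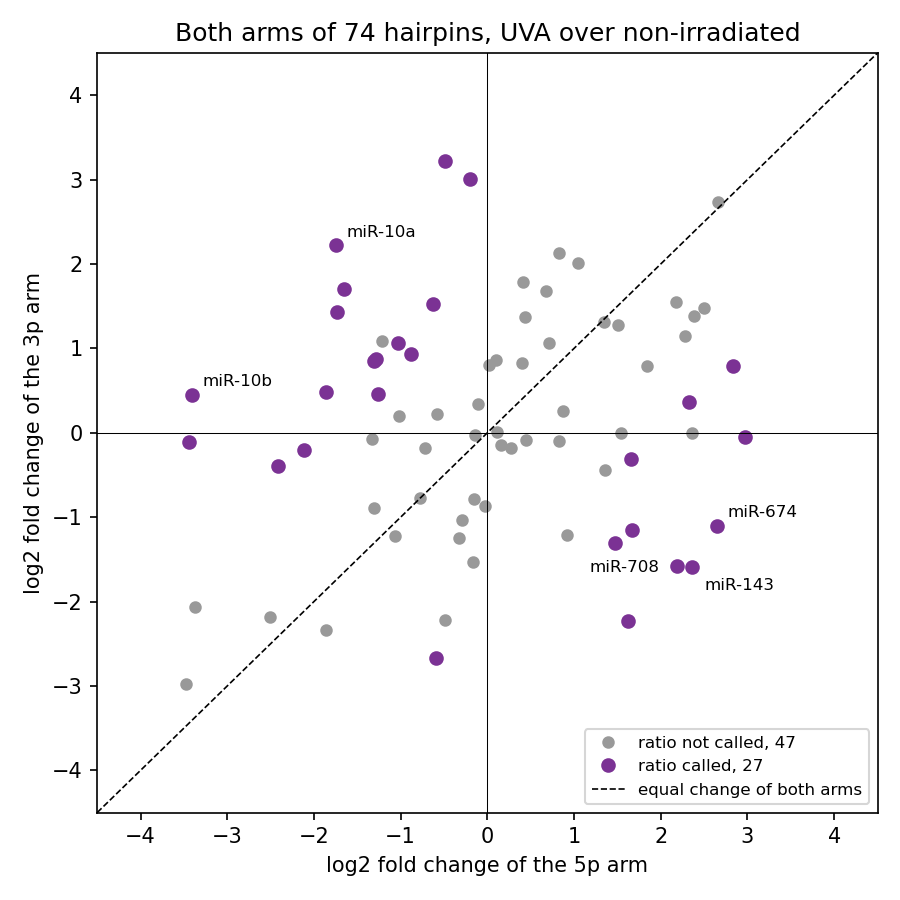
Log2 fold change of the 3p arm (y axis) against that of the 5p arm (x axis) for 74 hairpins, UVA over non-irradiated skin; the dashed line marks an equal change of both arms. The 27 hairpins whose arm ratio was called lie away from the line, among them miR-10a with -1.74 for its 5p and 2.23 for its 3p arm.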

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

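The tests of low read numbers per library were chosen after the result was seen, and the tests of depth, of abundant miRNAs and of predicted miRNAs were planned before. Among the 981 miRNAs below the count filter, left out of the main comparison of single miRNAs, 142 had a read in each of the 3 UVA libraries and none in the non-irradiated libraries, and 0 showed the opposite. These 142 held 2110 reads over the UVA libraries, with at most 55 reads of a single miRNA in a library.

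The pattern belongs to a wider one, the larger number of miRNAs detected in each UVA library. Depth as the cause is argued against by thinning to the same total, after which the lowest UVA library still had 274.5 more miRNAs than the highest non-irradiated library, and the gap was 181 without the 10 most abundant miRNAs and 194.5 among known miRNAs alone. A minimum count per miRNA set before deposit is argued against too, because non-irradiated replicates 1 and 2 still held at least 21 miRNAs with 1 to 9 reads. What these 2 libraries lack is low counts: the ratio of miRNAs with 1 to 9 reads to those with 10 to 29 reads was at most 0.225 there, against 4.39 to 4.81 in the UVA libraries, which is consistent with few distinct RNA molecules each read many times. In non-irradiated replicate 3 the ratio of 3.4 lay between, and few molecules and a biological loss of rare miRNAs cannot be told apart there, since the group has no other library with low counts.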

How the results depend on the processing

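The scaling to the authors' total reads, the GC offset and the fits without non-irradiated replicates 1 and 2 were chosen after the result was seen. Where no cause is named, the cause was not tested. Against 109 calls over all miRNAs (68 higher, 41 lower), the DESeq2 Wald test called 178, an adjusted p of 0.1 gave 182 by its looser threshold, and the authors' total reads gave 167. Without single libraries the count ranged from 38 to 124. Without non-irradiated replicates 1 and 2 it was 1, with the lone non-irradiated library assumed to vary like the others and fewer samples in the test. The other settings gave 98 to 151 calls. Against 6 called lists, the estimated correlation gave 0 (1 list, Dlk1-Dio3, at an unadjusted p of 0.0322), fry gave 10 (also skeletal muscle, epithelial, miR-29 and hair cycle), single libraries left out gave 2 to 7 and the fit without non-irradiated replicates 1 and 2 gave 2. Against 27 called hairpins, single libraries left out gave 16 to 28 and the fit without non-irradiated replicates 1 and 2 gave 4. The difference in the share of the 10 most abundant miRNAs kept its sign without each single library, and without the most abundant miRNA the share of the next 10 differed by -3.004 percentage points (exact permutation p = 0.5). Leaving out single libraries moved the latter difference from -5.494 to -0.674 percentage points.

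Whether the replicate numbers pair the libraries is not known. Deviations of same-numbered libraries from their group means correlated at 0.085, -0.076 and -0.027, and only replicate 1 correlated best with its own number. With so few libraries these correlations cannot tell whether the libraries were paired. With the replicate block, 106 miRNAs (61 higher, 45 lower), 4 lists and 17 hairpins were called.

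Signs changed for miRNAs and lists that were not called. With library size only the log2 fold change was 0.51 for miR-133a-3p, 0.34 for miR-126a-3p, 0.23 for miR-21a-5p and 0.036 for miR-24-3p, and with the authors' total reads these were 0.78, 0.51, 0.47 and 0.22. miR-133a-3p was 0.015 with the DESeq2 Wald test and 0.0029 with 10 or more counts in each library, and miR-21a-5p was 0.41 with the GC offset. Without non-irradiated replicates 1 and 2, miR-26a-5p was -0.17, miR-451a -0.00012 and let-7f-5p -0.16. Leaving out single libraries gave -0.48 to 0.15 for miR-133a-3p, -0.85 to 0.87 for miR-451a, -0.12 to 0.36 for miR-26a-5p and -0.23 to 0.35 for let-7f-5p. List directions turned at an adjusted p of 0.993 (authors' total reads), 0.986 (GC offset) and 0.752 (fry) for vascular, 0.752 (fry) for Hox, and 0.995 (replicate block) and 0.475 (without non-irradiated replicates 1 and 2) for leukocyte miRNAs. Leaving out single libraries gave list p from 0.748 to 0.928 for leukocyte, 0.625 to 0.939 for Hox, 0.623 to 0.939 for neural and 0.801 to 0.993 for vascular miRNAs.

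Over the other values of named miRNAs, 1187 kept their direction and side of the threshold, 228 lost the call and 40 gained it. For lists these were 221, 26 and 8. The Dlk1-Dio3 and Sfmbt2 lists kept their calls in all settings run except the estimated correlation. camera compares a list with the other miRNAs, so a change of scaling alone can move its result little. fry was run with TMM scaling only, so the kept calls do not test the dependence on scaling. In simulated data 5.07% of 2-fold changes were called, and how this depends on depth was not tested.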

Other observations

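The arm tests on GC content, counting noise, few molecules and batch, the miR-1a to miR-133a ratio and the mean of the muscle list were chosen after the result was seen. Of 24 predicted miRNAs tested with edgeR, 3 were higher and 4 lower in UVA skin. Across the 74 hairpins, the log2 fold changes of the arms were weakly related: Pearson's r was 0.184 (permutation p = 0.118) and Spearman's rho 0.138 (permutation p = 0.238), across hairpins, which are not independent replicates. Whether arms of a hairpin moved together in most hairpins was left open by this test. Among these 74, both arms were called by edgeR in 5, in the same direction in 3 and in opposite directions in miR-10a and miR-143. Outside them, both arms of miR-31, miR-199a, miR-210, miR-211 and miR-222 were called higher and of miR-542 lower, and miR-182 had its 5p arm lower and its 3p arm higher.

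Arms of a hairpin that moved apart may reflect changed strand selection or a technical effect. GC content is argued against by 26 of the 27 hairpins being called after a per-library GC correction, counting noise near the floor by 23 calls among 63 hairpins with a mean of 100 or more reads on both arms (18 of 40 with 100 or more in each library), and shared reads by 22 calls among 51 hairpins without a partner within 2 edits. Few RNA molecules in the non-irradiated libraries stay open: 11 of 22 hairpins with a mean of 1000 or more reads were called, but 0 of the 8 with 1000 or more reads in each library. A batch that follows the treatment cannot be told apart from it, since total reads do not overlap (exact permutation p = 0.1). The 10 splits of the 6 libraries are too few to judge chance, with 27 calls in the real split (1 of 10 with as many) and at most 0 in the others.

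miR-1a-3p and the Dlk1-Dio3 miRNAs, which are abundant in skeletal muscle, were both lower, and less muscle in the irradiated pieces is a candidate explanation. As the only cause of the changes in muscle miRNAs it is argued against by the log2 ratio of miR-1a-3p to miR-133a-3p, from neighbouring hairpins. That ratio was 6.44 ± 1.03 in UVA and 9.72 ± 0.57 in non-irradiated skin (difference -3.28, SE 0.68). What else moved the ratio may be technical, since arm ratios also changed in 27 of 74 hairpins. miR-133a-3p also lies 1 edit from miR-133b-3p, which rose. The ratio therefore cannot tell how much of the fall of miR-1a-3p came from less muscle. Less muscle as a part of the cause stays open, because the fall of the muscle list itself depends on the scaling. The mean log2 CPM of that list differed by -0.98 (SE 0.18, 6 of 7 members negative, fry adjusted p = 0.0356). It differed by -0.45 (SE 0.23, 4 of 7 negative) with library size alone and by -0.23 (SE 0.32, 4 of 7 negative) with the authors' total reads. Less muscle stays open for the Dlk1-Dio3 miRNAs too, since their mean log2 CPM less that of the muscle list changed by -0.56 (SE 0.36). With the 10 most abundant miRNAs left out of the scaling, 15 Dlk1-Dio3 miRNAs were called lower. That setting still used TMM, which trims extreme miRNAs in either case, so it cannot tell how far scaling matters. The size of the fall did depend on the scaling. With library size alone and with the authors' total reads, 10 and 9 members were called lower. The list mean then differed by -1.03 (SE 0.29) and -0.82 (SE 0.18), against -1.53 (SE 0.28) in the main fit. An effect of UVA remains untested beyond the comparison itself.

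The same 10 splits, too few for a share under 0.05, gave 109 called miRNAs in the real split. In the others at most 0 were called (1 of 10 as large). The real split called 6 lists (1 of 10 as large), and each other split called 2 to 5 lists while calling 0 miRNAs. Thus camera at the preset correlation of 0.01 also called lists when the groups were mixed, and 6 lies little above that range.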
